A study of Mus musculus with 18 samples.

How the data were processed

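The series holds 18 mouse gene expression arrays. RNA came from spermatocytes sorted by flow cytometry from males aged 2 months and from whole testes, with the outer coat removed, of males aged 15 days. The sorted arrays cover pre-mid-pachytene spermatocytes of Ttf/T43H carriers (n = 3), t12/T43 carriers (n = 3) and C57BL/10J males (n = 2), and mid-late-pachytene spermatocytes of C57BL/10J males (n = 2). The testis arrays cover Ttf/T43H carriers (n = 3), t12/T43 carriers (n = 3) and C57BL/6J males (n = 2). Groups and replicate numbers were taken from the sample titles. The design text calls the replicates biological.

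The authors deposited log2 values made with GCRMA, which corrects for background, normalizes across arrays and summarises probes, per the submitters' processing notes. The notes give no GCRMA version, and they do not say which arrays were normalized together. Per the labels, 20 to 30 ng of RNA went through a 2-cycle biotin labelling. The genome build and any filter were not given in the sources used here. The table has 16539 probe sets, from a custom chip definition with 1 probe set per Entrez gene. Of these, 15780 carry 1 gene symbol, 0 carry several, and 759 carry no gene symbol, 64 of them array controls. The unnamed probe sets were left out of every test. A mouse gene annotation table, GRCm38.p6, was used only for gene names, chromosomes and the order of neighbouring genes, and placed 15749 named genes. Arrays give no read depth, and the number of arrays limits the precision. The median of all probe sets lay between 4.53 and 5.66 on the log2 scale in every group, and between 54.2% and 57.0% of probe sets reached a log2 value of 4, so values near or below that level carry little signal over background.

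The values were used as deposited. A gene was tested where at least 2 arrays of its fit had a log2 value of at least 4. The sorted cells (10 arrays, 9666 genes) and the testes (8 arrays, 9134 genes) were fitted separately with limma 3.58.1 in R 4.3.3, by lmFit with 1 mean per group and eBayes. A further fit of all 18 arrays (10623 genes) tested whether the difference between t12/T43 and Ttf/T43H carriers itself differed between sorted cells and testes. Tests were two-sided, p-values were adjusted by Benjamini and Hochberg's method over all genes of a comparison, and an adjusted p under 0.05 is called. Errors of log2 changes are limma's moderated standard errors (SE), and n is the number of arrays per group. Both carrier groups were compared with the same control arrays within each tissue, so those comparisons share the error of the controls.

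Chromosomes and gene lists were tested with camera at a preset correlation of 0.01, which asks whether the genes of a set moved more than the other genes. The same test with a correlation estimated from the residuals was run beside it, as was fry, which asks whether the genes of a set move, on balance, in 1 direction and does not compare them with other genes. Adjusted p-values of sets are over 22 chromosome sets or 19 gene lists per comparison. Chromosome 17 was divided into a proximal part, whose last gene is Esp38, and a distal part, whose first gene is Pgk2. The array names 436 genes of proximal 17, 307 of distal 17, 508 of chromosome 16, 542 of the X and 6 of the Y. The lists hold 398 genes, 317 of them on the array. They are X housekeeping, X germ cell, Y linked, autosomal retrocopies of X genes, synapsis and chromosome axis, meiotic recombination, DNA damage signalling and meiotic silencing, p53 targets and apoptosis, mid-late pachytene and meiotic division, round and elongating spermatid, spermatogonia and preleptotene, leptotene and zygotene, Sertoli cell, Leydig cell, peritubular and endothelial cell, macrophage and blood cell, t complex, piRNA pathway, and heat shock and immediate early stress. For each list, the number of called members is given over all genes tested and adjusted over the list alone.

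Per array, the level of a chromosome is its mean over tested genes minus the mean of autosomes other than 16 and 17. These levels were compared with exact two-sided permutation tests in a family of 27. The smallest p possible is 0.1 for 3 arrays against 3, 0.2 for 3 against 2 and 0.3333 for 2 against 2, so none of them can pass the threshold.

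Named genes were chosen by a rule. For each comparison it takes the 8 largest rises and 8 largest falls among called genes whose group ranges did not overlap and whose name is not that of a clone or predicted gene. It adds up to 4 tested members with the smallest p of each list, the X, the Y, proximal and distal 17 and chromosome 16, and always Zfy1 and Zfy2 where the array has them. The text may name fewer, and may name a gene in another comparison to set its values side by side.

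The comparisons, lists, filter, tests, naming rule and the alternative settings below were fixed before the data were examined. The alternatives were no filter, a filter at a log2 value of 6, quantile normalization, centring each array on other autosomes, limma with trend and robust options, array weights, only the 2 groups compared, a replicate block, a 2-fold minimum, nearer borders of proximal 17, an X chromosome without multicopy families, an estimated correlation, and leaving out each array in turn. Leaving out both arrays that stand apart from their groups was added after seeing the data. Where leaving out an array left 1 in a group, the lone array was assumed to vary like the other groups.

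The fits were tested on simulated data with the same designs, using 9666, 9134 and 10623 genes of which 200 changed. Noise was drawn independently for each gene, with no deviation shared by the genes of an array. The shares recovered hold for that setting and need not hold in the real comparisons, where other numbers of genes changed. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.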

Results

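Gene expression was measured on 18 mouse arrays, from 10 samples of sorted spermatocytes and 8 whole testes of 15-day-old males. The carriers combine T43H, a reciprocal translocation between chromosomes 16 and 17, with either the Ttf or the t12 chromosome 17, on a C57BL/10J background. As background, t haplotypes are variants of proximal chromosome 17 that carry inversions. Pre-mid-pachytene spermatocytes came from Ttf/T43H (n = 3), t12/T43 (n = 3) and fertile C57BL/10J males (n = 2), and mid-late-pachytene spermatocytes from C57BL/10J males (n = 2). The testes came from Ttf/T43H (n = 3), t12/T43 (n = 3) and C57BL/6J males (n = 2). The study's title asks about the meiotic consequences of extending unsynapsed autosomal chromatin. Values are the authors' log2 GCRMA values, with no read depth, and changes are log2 differences with their SE.

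In the sorted cells, the mean level of the X relative to other autosomes was -0.56 ± 0.57 in Ttf/T43H, -0.36 ± 0.43 in t12/T43 and -0.44 ± 0.03 in C57BL/10J pre-mid-pachytene cells, and -3.91 ± 0.09 in mid-late-pachytene cells (SD). The level of proximal 17 was -0.55 ± 0.31, -0.80 ± 0.05, -0.21 ± 0.01 and 0.06 ± 0.02 in the same groups. In testes, proximal 17 stood at -0.52 ± 0.0022 in Ttf/T43H, -0.53 ± 0.0017 in t12/T43 and -0.29 ± 0.01 in C57BL/6J. The X stood at 0.17 ± 0.07, 0.37 ± 0.04 and 0.18 ± 0.02 there. In 27 exact two-sided permutation tests of such levels, no adjusted p fell under 0.3, and the smallest p possible is 0.1 for 3 arrays against 3, 0.2 for 3 against 2 and 0.3333 for 2 against 2. Pearson correlations between replicate arrays, across genes, ran from 0.963 to 0.996 in sorted cells and from 0.998 to 0.999 in testes. Among sorted arrays, Ttf/T43H replicate 2 and t12/T43 replicate 3 stood apart from their groups, with X levels of 0.05 and 0.13 where the other carrier arrays lay between -1.09 and -0.52. The 3' minus 5' signal of Gapdh, a sign of RNA and labelling quality, moved with genotype among the sorted arrays. It lay between 3.26 and 3.98 in the 6 carrier arrays and at 2.86 and 2.93 in C57BL/10J pre-mid-pachytene arrays, and that of actin lay between 3.06 and 4.41 and at 2.49 and 2.51. Ttf/T43H replicate 2, which stood apart, had 4.41 for actin against 3.25 and 3.06 in its group, and 3.91 for Gapdh against 3.43 and 3.26. The other such array, t12/T43 replicate 3, lay between the other 2 of its group for both, at 3.48 and 3.80. Mid-late arrays had 2.51 and 3.39 for Gapdh and 3.51 and 3.38 for actin. In testes the group means of Ttf/T43H, t12/T43 and C57BL/6J were 0.03, -0.01 and -0.10 for Gapdh and 1.24, 1.18 and 1.16 for actin.

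**Figure D1:**
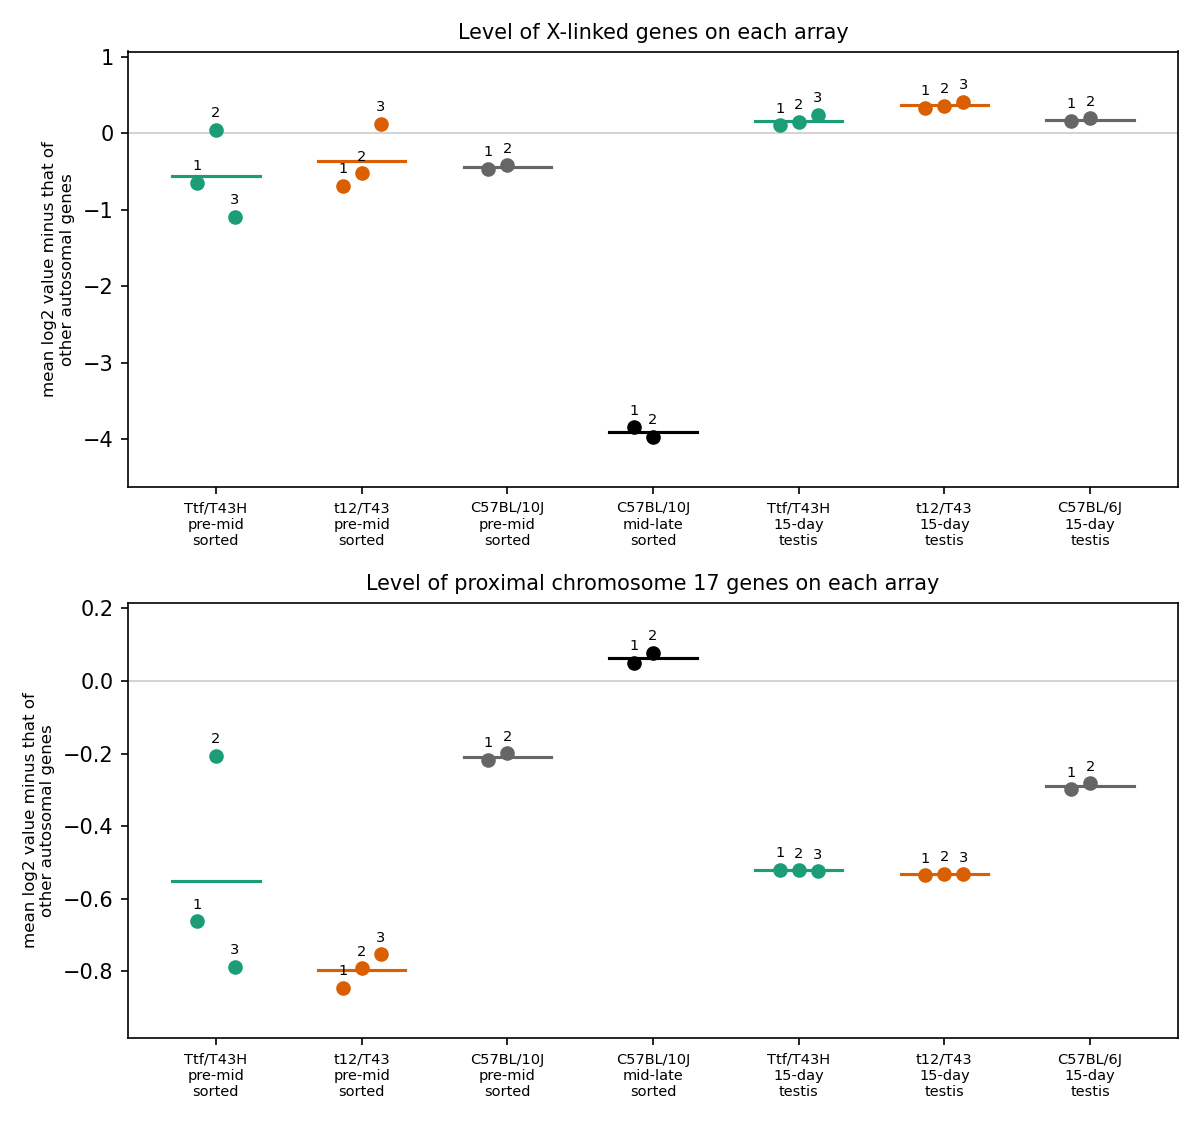
Mean level of the X and of proximal chromosome 17 relative to autosomes other than 16 and 17, in log2 units, for each array (points with replicate numbers) and each group (horizontal lines at the mean). Mid-late-pachytene cells have X levels of -3.84 and -3.97, and testes of both carriers have lower proximal 17 levels (-0.52 and -0.53) than C57BL/6J testes (-0.29).

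Comparing t12/T43 with Ttf/T43H pre-mid-pachytene spermatocytes sets the t12 against the Ttf chromosome 17, since both groups carry the translocation. The mean 3' minus 5' signal was 3.74 and 3.53 for Gapdh and 3.53 and 3.57 for actin in these groups. Transcripts of late spermatogenesis were lower in t12/T43 sorts. Spermatid RNA carried into the sorts may account for this, so the fall need not lie in spermatocytes. Of 24 measured genes of the spermatid list, 6 fell and 18 did not pass (18 fell adjusted over the list alone), with a median of -3.70. Tnp2, a transition protein of spermatid chromatin, fell by 5.83 ± 0.48 (56.8-fold, adjusted p = 0.0042, n = 3 and 3). Prm2, a protamine, fell by 4.44 ± 0.37, the sperm glycolytic enzyme gene Gapdhs fell by 4.88 ± 0.45, and the acrosomal gene Acrv1 fell by 4.26 ± 0.60. Outside the list, the testis genes Spata19, Hspb9, Hmgb4 and Stat4 fell by 4.79 ± 0.51, 4.76 ± 0.51, 4.76 ± 0.74 and 4.56 ± 0.61. The list's adjusted p was 4.8e-25, and the adjusted p = 0.18 with an estimated correlation, while fry gave 0.036. Its level per array was -2.54, -0.35 and -2.84 in t12/T43, between 0.80 and 1.17 in Ttf/T43H, and 2.91 and 2.37 in C57BL/10J pre-mid-pachytene cells.

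In the same comparison, 2 of 34 genes of the mid-late pachytene list fell (9 adjusted over the list alone), with a median of -0.58. Spink2, a protease inhibitor of germ cells, fell by 2.29 ± 0.27, and Tcp11 fell by 2.73 ± 0.38. The list's adjusted p was 2.2e-07, with an adjusted p = 0.52 with an estimated correlation. Of 15 t complex genes, Tcp11 and Tcte2 (fell by 2.46 ± 0.41) fell (1 rose and 4 fell adjusted over the list alone), with an adjusted p of 0.0046 and an adjusted p = 0.18 with an estimated correlation. On distal 17 the sperm thioredoxin gene Txndc2 fell by 3.29 ± 0.57. On chromosome 16, which also holds Tnp2 and Prm2, Septin12 and Ccdc54 fell by 2.92 ± 0.44 and 2.93 ± 0.47. Cd36, Cth, Emp1, Sphk1 and the linker histone gene H1f2 rose by 2.62 ± 0.35, 2.43 ± 0.31, 1.82 ± 0.29, 1.70 ± 0.18 and 1.43 ± 0.21. The Leydig and Sertoli lists moved with the group, though no member passed in limma: the Leydig list had a median of 1.25 over 7 genes (adjusted p = 0.0069, and adjusted p = 0.71 with an estimated correlation) and the Sertoli list 0.58 over 14 genes (0.0091, and adjusted p = 0.71 with an estimated correlation). Hsd3b1, a steroid-making enzyme gene, had a change of 2.37 ± 0.87 (adjusted p = 0.36), and Inha, a Sertoli cell hormone subunit, 1.09 ± 0.39 (0.35).

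Limma called 6 genes higher and 67 lower in t12/T43 among 9666 (987 with an unadjusted p under 0.05, where chance gives 483). With a replicate block, a pairing the labels do not give, limma called 0 (869 unadjusted). The count was 26, 24 and 14 without Ttf/T43H replicate 1, 2 and 3 and 23, 411 and 13 without t12/T43 replicate 1, 2 and 3, and limma called 0 (825 unadjusted) without both arrays that stand apart, a setting chosen after seeing the data. Of the 19 called genes named above, 6 kept their call whichever array was left out. The Sertoli list lost its call without Ttf/T43H replicate 2 (0.11) or t12/T43 replicate 3 (0.54), the Leydig list without Ttf/T43H replicate 3 (0.093) or t12/T43 replicate 3 (0.086), and the t complex list without Ttf/T43H replicate 2 (0.063). Proximal 17 had a median of -0.18, with 2 of 276 genes called, an adjusted p of 1.4e-04, an adjusted p = 1.0 with an estimated correlation, and 0.68 without Ttf/T43H replicate 2. The X had a median of 0.21 with none of 301 genes called by limma (adjusted p = 0.055); it was called without Ttf/T43H replicate 2 (3.8e-12) or t12/T43 replicate 1 (2.4e-05), and turned direction without Ttf/T43H replicate 3 (0.79) or t12/T43 replicate 3 (0.98). Zfy2, Stag2, Dmc1 and Atf3 had changes of 0.82 ± 0.57, 0.44 ± 0.39, 0.32 ± 0.21 and 1.91 ± 0.41 (adjusted p = 0.76, 0.83, 0.73 and 0.087). No other list was called: adjusted p was 0.46 for X housekeeping, 0.15 for X germ cell, 0.36 for Y linked genes, retrocopies and heat shock, 0.56 for synapsis, 0.76 for recombination, 0.86 for DNA damage, 0.39 for p53 targets and spermatogonia, 0.83 for leptotene and zygotene, 0.16 for peritubular cells, 0.41 for macrophages and 0.42 for the piRNA pathway. On simulated data of 9666 genes with 200 changed, 15% of those changed 2-fold and 64% of those changed 4-fold were recovered.

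**Figure D2:**
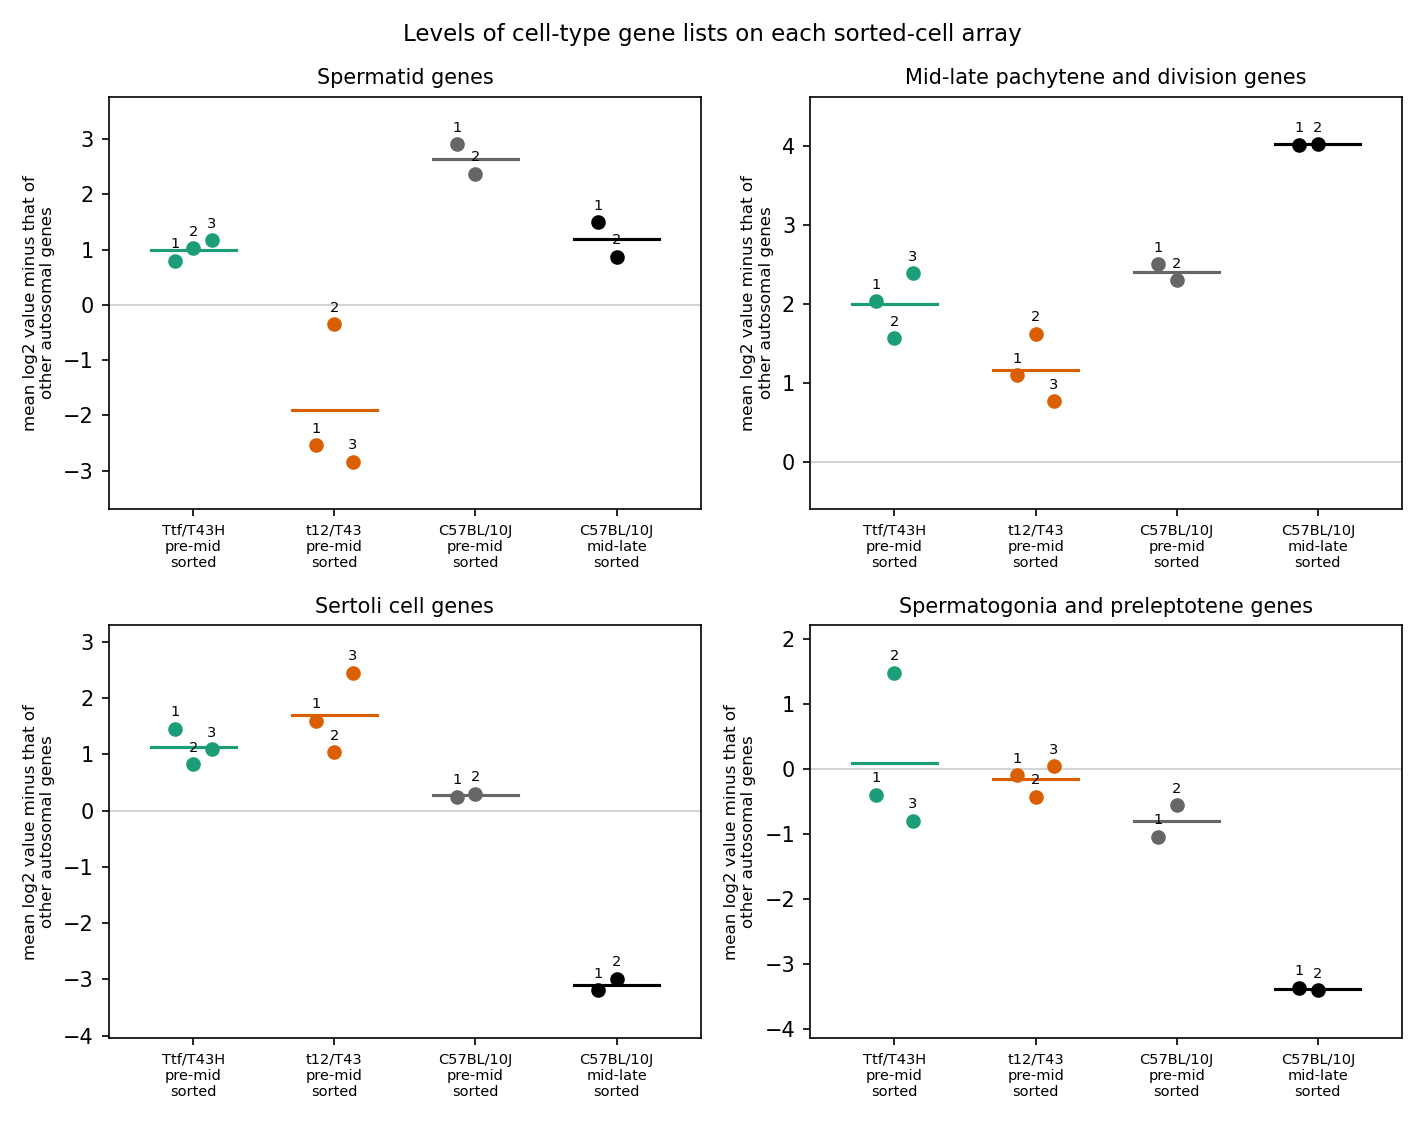
Mean level of the spermatid, mid-late pachytene, Sertoli and spermatogonia lists relative to autosomes other than 16 and 17, in log2 units, for each sorted-cell array (points with replicate numbers) and each group (horizontal lines at the mean). The spermatid list lies at -2.54, -0.35 and -2.84 in t12/T43 and at 2.91 and 2.37 in C57BL/10J pre-mid-pachytene cells.

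Comparing Ttf/T43H with C57BL/10J pre-mid-pachytene spermatocytes asks what the translocation with the Ttf chromosome changes. The 3' minus 5' signal was higher in the carrier too, at means of 3.53 against 2.90 for Gapdh and 3.57 against 2.501 for actin, beside every gene group below. Genes of proximal 17 were lower in the carrier: of 276 measured, 17 fell and 259 did not pass (3 rose and 44 fell adjusted over the set alone), with a median of -0.18. The class I antigen gene H2-K1 fell by 3.20 ± 0.33 (adjusted p = 0.0039, n = 3 and 2), the meiotic recombination gene Hsf2bp fell by 1.90 ± 0.19, Rnf5 fell by 2.53 ± 0.31 and the class II antigen gene H2-Ab1 fell by 2.22 ± 0.24. The adjusted p was 1.6e-04, with an adjusted p = 0.93 with an estimated correlation. On distal 17, Acsbg2 fell by 4.25 ± 0.31. On the X, the muscle gene Smpx fell by 5.03 ± 0.34, and of 16 X germ cell genes Actrt1 and Tex13a fell by 3.62 ± 0.44 and 2.48 ± 0.43 (4 fell adjusted over the list alone; adjusted p = 0.0020, and adjusted p = 0.59 with an estimated correlation). The X germ cell list also holds the sperm tail gene Akap4, which stood at 10.42 in Ttf/T43H and 13.01 in C57BL/10J. Of 4 Y genes, Uty fell by 2.00 ± 0.23, and Zfy2 had a change of -1.18 ± 0.64 (adjusted p = 0.39). The Y list had an adjusted p of 0.0076, with an adjusted p = 0.59 with an estimated correlation. Outside these groups, Pdzk1, Eya4 and Ubl4b fell by 4.48 ± 0.71, 3.67 ± 0.48 and 3.09 ± 0.31.

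Of 24 spermatid genes, Prm2 fell by 2.46 ± 0.42 in Ttf/T43H and 23 did not pass (4 fell adjusted over the list alone), with a median of -1.53, an adjusted p of 1.8e-07 and an adjusted p = 0.59 with an estimated correlation. The piRNA factor gene Tdrkh, the DNA repair gene Brca1 and the smooth muscle actin gene Actg2 fell by 1.51 ± 0.24, 1.08 ± 0.21 and 2.80 ± 0.54, and Spink2 rose by 1.54 ± 0.31. Among rises, the interferon-responsive genes Ly6e and Ifi202b rose by 3.39 ± 0.66 and 3.02 ± 0.60, the chemokine gene Cxcl2 rose by 3.39 ± 0.61, the apolipoprotein gene Apoc2 rose by 3.01 ± 0.53, and Spen, Mta1 and Trim32 rose by 2.96 ± 0.38, 2.56 ± 0.51 and 2.51 ± 0.27. Of the other lists, 4 were called with higher medians and no member passing in limma over all genes: Sertoli 0.88 (1 adjusted over the list alone, adjusted p = 0.0021), Leydig 1.01 (2, 0.0074), heat shock and immediate early stress 1.01 (3, 0.0021) and spermatogonia 0.96 (adjusted p = 0.035). With an estimated correlation these had adjusted p = 0.72, 0.59, 0.59 and 0.77. Cyp11a1, Wt1 and Fosb had changes of 4.18 ± 1.13, 2.13 ± 0.48 and 3.29 ± 0.72 (adjusted p = 0.098, 0.062 and 0.059). The peritubular and macrophage lists were not called (adjusted p = 0.69 each). The spermatogonia list stood at 1.48 in Ttf/T43H replicate 2 and at -0.39 and -0.79 in the other two.

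Limma called 57 genes higher and 142 lower in Ttf/T43H (1731 with an unadjusted p under 0.05). The count was 36, 368 and 75 without Ttf/T43H replicate 1, 2 and 3, 0 (850 unadjusted) without C57BL/10J replicate 1, 7 without C57BL/10J replicate 2, and 542 without both arrays that stand apart, and of the 24 called genes named none kept its call in every one of the fits that left out 1 array. Proximal 17 lost its call without Ttf/T43H replicate 3 (0.12), the Y list without C57BL/10J replicate 1 (0.24) or 2 (0.13), and the spermatogonia list without Ttf/T43H replicate 2 (0.61) or C57BL/10J replicate 1 (0.17). The X had a median of -0.03 with 7 genes lower (adjusted p = 0.60); it was called lower without Ttf/T43H replicate 2 (8.5e-05) and turned direction without replicate 3 (0.45). On simulated data with 200 changed genes, 12% of those changed 2-fold and 58% of those changed 4-fold were recovered.

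Comparing t12/T43 with C57BL/10J pre-mid-pachytene spermatocytes asks the same of the t12 chromosome. The 3' minus 5' signal was again higher in the carrier, at means of 3.74 against 2.90 for Gapdh and 3.53 against 2.501 for actin. The spermatid list was lower: 20 of 24 genes fell and 4 did not pass (21 adjusted over the list alone), with a median of -5.22. Prm2 fell by 6.91 ± 0.42 (adjusted p = 1.4e-04, n = 3 and 2), and Tnp2, Gapdhs and the outer dense fibre gene Odf1 fell by 6.43 ± 0.54, 6.69 ± 0.51 and 7.01 ± 1.20. Prm2 and Tnp2 lie on chromosome 16, a partner in the translocation, and Gapdhs lies on chromosome 7. Outside the list, the sperm tail gene Akap4 and Oxct2a fell by 6.35 ± 1.19 and 7.08 ± 1.15. The list's adjusted p was 8.6e-22, with an adjusted p = 0.24 with an estimated correlation and 0.0063 from fry. Of 34 mid-late pachytene genes 6 fell (14 adjusted over the list alone, adjusted p = 3.3e-05, and adjusted p = 0.45 with an estimated correlation), among them Tcp11 by a log2 change of -4.56 ± 0.42, the testis glycolytic enzyme gene Pgk2 by -4.48 ± 0.78 and the testis heat shock gene Hspa1l by -6.68 ± 1.22. Tcp11, Pgk2 and Hspa1l all lie on chromosome 17, where carriers and controls differ, so their falls need not reflect stage. Tcp11 is also in the t complex list.

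Proximal 17 was lower in t12/T43 as well: of 276 genes, 2 rose, 56 fell and 218 did not pass (3 and 67 adjusted over the set alone), with a median of -0.49, an adjusted p of 1.2e-09 and an adjusted p = 0.98 with an estimated correlation. Hsf2bp, Hagh, H2-Ab1, the ubiquitin ligase gene Rnf8, which acts in DNA damage signalling, Tbp and Tcp10c fell by 1.85 ± 0.19, 2.09 ± 0.24, 2.02 ± 0.24, 1.19 ± 0.25, 1.20 ± 0.26 and 5.60 ± 1.41. Of 15 t complex genes 4 fell (4 adjusted over the list alone, adjusted p = 0.0039, and adjusted p = 0.24 with an estimated correlation). Of 16 X germ cell genes 3 fell (5 adjusted over the list alone, adjusted p = 1.1e-04, and adjusted p = 0.42 with an estimated correlation), with Actrt1 at -4.47 ± 0.44. This list also holds the sperm tail gene Akap4, which stood at 6.66 in t12/T43 and 13.01 in C57BL/10J. Its call is therefore not separate from the fall of spermatid transcripts. Smpx, Uty, Actg2 and Tdrkh fell by 5.03 ± 0.34, 1.95 ± 0.23, 5.33 ± 0.54 and 1.15 ± 0.24, and Zfy2 had a change of -0.35 ± 0.64 (adjusted p = 0.86).

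Markers of Leydig and Sertoli cells were higher in t12/T43. Of 7 Leydig genes 2 rose (7 adjusted over the list alone), with a median of 3.38, and Cyp11a1, a steroid-making enzyme gene, and Ptgds rose by 5.42 ± 1.13 and 4.24 ± 0.78 (adjusted p = 1.1e-04 for the list, and adjusted p = 0.42 with an estimated correlation). Of 14 Sertoli genes 4 rose (9 adjusted over the list alone), with a median of 1.19, among them Wt1, Cldn11 and Inha, which rose by 2.89 ± 0.48, 2.41 ± 0.52 and 1.79 ± 0.43 (adjusted p = 3.3e-05 for the list, and adjusted p = 0.45 with an estimated correlation). Of 8 peritubular and endothelial genes Actg2 alone passed, and it fell (1 adjusted over the list alone; median 0.18, adjusted p = 0.82). None of 3 macrophage genes passed in limma (median 1.18, adjusted p = 0.39). Of 15 stress genes 4 rose (6 adjusted over the list alone), with Fosb rising from a mean of 3.33 to 7.33 and Jun and Atf3 rising by 1.98 ± 0.45 and 2.27 ± 0.45 (adjusted p = 6.4e-04 for the list, and adjusted p = 0.45 with an estimated correlation). The inflammatory genes Cxcl2, Cxcl1 and Il1a rose by 5.92 ± 0.61, 4.64 ± 0.82 and 4.69 ± 0.89, and Bhmt, Klk1b24, Agt and Ly6e rose by 5.93 ± 1.27, 5.30 ± 0.82, 5.11 ± 0.85 and 4.95 ± 0.66. The Leydig list stood at -0.32, 0.32 and 2.02 in t12/T43 replicates and at -2.20 and -3.45 in C57BL/10J, and the Sertoli list at 1.60, 1.03 and 2.44 against 0.24 and 0.29.

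Limma called 313 genes higher and 564 lower in t12/T43 (2133 with an unadjusted p under 0.05). The count was 581 without t12/T43 replicate 3, 1391 without replicate 2, and 141 and 267 without C57BL/10J replicate 1 and 2, and 10 of the 35 called genes named kept their call in every fit that left out 1 array. The X had a median of 0.11 with 12 genes higher and 14 lower, while its test pointed down (adjusted p = 0.98) and pointed up without t12/T43 replicate 3 (0.71). On simulated data with 200 changed genes, 16% of those changed 2-fold and 54% of those changed 4-fold were recovered. For many of the genes named in sorted cells, and for several in testes, the lower group mean lay below a log2 value of 4, near the low end of the arrays, where a change is less certain in size.

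Comparing mid-late with pre-mid-pachytene spermatocytes of C57BL/10J asks how expression moves as normal pachytene advances. The 2 sorts also differed in markers of other cells, so a change between them cannot be assigned to stage alone. The Sertoli list stood at -3.09 in mid-late and 0.27 in pre-mid sorts, and the spermatogonia list at -3.38 and -0.80. The mean 3' minus 5' signal was 2.95 against 2.90 for Gapdh and 3.44 against 2.501 for actin. The X chromosome was lower at the later stage: of 301 genes 220 fell, 5 rose and 76 did not pass, with a median of -3.60 (adjusted p = 1.2e-17, adjusted p = 0.98 with an estimated correlation, and fry 0.0013). The X-linked genes Rhox13, Fmr1nb and Tktl1 fell by 10.71 ± 0.74, 10.45 ± 0.41 and 10.42 ± 0.41 (n = 2 and 2), with 12 of 16 in the X germ cell list falling (12 adjusted over the list alone, adjusted p = 1.6e-04). Of 15 X housekeeping genes 14 fell (14 adjusted over the list alone, adjusted p = 4.9e-05), among them the purine salvage gene Hprt by -7.34 ± 0.64 and the chromatin gene Rbbp7 by -7.25 ± 0.49. All 4 Y genes tested fell (4 adjusted over the list alone, adjusted p = 0.011), with Usp9y, Zfy2 and Eif2s3y at -8.42 ± 0.54, -4.11 ± 0.70 and -4.69 ± 0.45. Each of these 3 lists, and every list called in this comparison, had an adjusted p = 0.48 with an estimated correlation.

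Genes of early prophase were also lower in the mid-late sort, where stage and cell content cannot be told apart. Of 15 leptotene and zygotene genes 12 fell (12 adjusted over the list alone, adjusted p = 5.3e-04), with Dmc1 and Meiob, which act in recombination, and Stra8, which starts meiosis, falling by 8.30 ± 0.26, 5.17 ± 0.47 and 7.76 ± 0.90. In the synapsis list 10 of 15 fell and 1 rose (10 and 1 adjusted over the list alone, adjusted p = 0.0026), and in the DNA damage list 14 of 22 fell and 2 rose (15 and 2 adjusted over the list alone, adjusted p = 0.0026), with the kinase gene Atm at -7.22 ± 0.74 and Brca1 at -3.42 ± 0.23. The lists in this paragraph had an adjusted p = 0.48 with an estimated correlation. Sohlh2, Prss50 and Mov10l1 fell by 9.59 ± 0.61, 10.51 ± 0.38 and 3.57 ± 0.49. Genes of late pachytene rose: 16 of 34 in the list rose and 1 fell (15 and 1 adjusted over the list alone), with a median of 1.38 (adjusted p = 0.0020), and the cyclin gene Ccna1, Spink2, Zpbp and Cetn1 rose by 5.84 ± 0.50, 4.63 ± 0.33, 3.27 ± 0.32 and 3.66 ± 0.33. The list had an adjusted p of 0.076 with no filter on low values. Slc25a54, Tcte1 and the piRNA genes Henmt1 and Pld6 rose by 9.02 ± 0.35, 6.95 ± 0.30, 5.41 ± 0.82 and 2.25 ± 0.42.

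Sertoli cell transcripts were lower in the mid-late sort. Of 14 Sertoli genes 10 fell (10 adjusted over the list alone, adjusted p = 0.0020, and adjusted p = 0.48 with an estimated correlation), with Ctsl and Clu at -7.06 ± 0.40 and -5.24 ± 0.48. Lists of other cell types and of stress were not called. Of 8 peritubular and endothelial genes 3 fell (3 adjusted over the list alone, adjusted p = 0.30), of 3 macrophage genes 1 rose and 1 fell (1 and 1, 0.69). Of 7 Leydig genes 1 fell (0, 0.69), and of 15 stress genes 2 rose and 8 fell (3 and 8, 0.13). Dcn and Acta2 of the first list, Mrc1 of the second and Fos of the last fell by 5.03 ± 1.22, 3.69 ± 0.54, 2.52 ± 0.68 and 5.87 ± 0.52. Igf2r and H2-D1, on chromosome 17, fell by 4.44 ± 0.44 and 7.90 ± 0.41. Of the p53 targets, Ccng1 fell by 3.89 ± 0.57 and Zmat3 rose by 3.87 ± 0.50. Of 24 spermatid genes 6 fell and 1 rose, with a median of -2.03 (adjusted p = 0.13, and 0.0040 with no filter), and Prm2 and Tnp2 fell by 3.79 ± 0.46 and 4.44 ± 0.59. Limma called 2537 genes higher and 2927 lower at the later stage (5901 with an unadjusted p under 0.05), and the count lay between 3874 and 4324 with 1 array left out. The median of all genes moved by -0.11. On simulated data with 200 changed genes, 6% of those changed 2-fold and 36% of those changed 4-fold were recovered. Far more genes were called in the real data, which eases the adjusted threshold, so these shares do not carry over.

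Against the mid-late cells of C57BL/10J, the pre-mid-pachytene cells of both carriers had high sex chromosome expression, as did those of C57BL/10J. X levels were -0.56 in Ttf/T43H, -0.36 in t12/T43 and -0.44 in C57BL/10J pre-mid-pachytene cells, against -3.91 in mid-late cells. Y levels were 0.85, 1.31, 2.04 and -2.64 in the same order. In Ttf/T43H 217 of 301 X genes were higher and 8 lower, with a median of 3.49 (adjusted p = 1.0e-16, and adjusted p = 1.0 with an estimated correlation), and in t12/T43 224 were higher and 14 lower, with a median of 3.76 (adjusted p = 1.0e-15, and adjusted p = 1.0 with an estimated correlation). Hprt was higher by 6.55 ± 0.58 and 6.85 ± 0.58 in the 2 carriers, Rbbp7 by 6.98 ± 0.45 and 7.28 ± 0.45, and Zfy2 by 2.93 ± 0.64 and 3.76 ± 0.64. Of 34 mid-late pachytene genes 20 were lower in Ttf/T43H and 23 in t12/T43 (20 and 24 adjusted over the list alone; adjusted p = 3.1e-04 and 5.6e-05, and adjusted p = 0.45 and 0.39 with an estimated correlation), with Ccna1 at -5.81 ± 0.46 and -7.47 ± 0.46. In t12/T43 20 of 24 spermatid genes were lower (21 adjusted over the list alone; adjusted p = 1.7e-04, and adjusted p = 0.39 with an estimated correlation), with Prm2 at -3.12 ± 0.42. Limma called 3061 genes higher and 2764 lower in Ttf/T43H, and 3306 higher and 2918 lower in t12/T43 (6154 and 6535 with an unadjusted p under 0.05), in a contrast that joins stage and genotype. Sertoli markers were higher too, with 10 and 11 of 14 genes (10 and 11 adjusted over the list alone), medians of 5.16 and 5.98, an adjusted p of 4.0e-04 and 1.7e-04, and adjusted p = 0.45 and 0.39 with an estimated correlation. Of 15 stress genes 10 and 11 were higher and 2 lower in each (the same adjusted over the list alone; adjusted p = 0.018 and 0.011, and adjusted p = 0.45 and 0.39 with an estimated correlation). Of 7 Leydig genes 3 and 6 were higher (3 and 6 adjusted over the list alone), with an adjusted p of 0.17 in Ttf/T43H and 0.045 in t12/T43 (adjusted p = 0.39 with an estimated correlation). The t12/T43 call was lost without t12/T43 replicate 2 (0.070), mid-late replicate 1 (0.078) or 2 (0.058), or both arrays that stand apart (0.067). The mean 3' minus 5' signal was 3.53 and 3.74 against 2.95 for Gapdh and 3.57 and 3.53 against 3.44 for actin. Proximal 17 had medians of -0.32 (adjusted p = 0.16) and -0.51 (0.021, with an adjusted p = 1.0 with an estimated correlation), and in Ttf/T43H it was called without replicate 2 (0.027). The median of all genes moved by 0.13 and 0.16. On simulated data with 200 changed genes, 4% and 19% of those changed 2-fold and 57% and 55% of those changed 4-fold were recovered. These shares do not carry over to the real data either, where far more genes were called.

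Comparing t12/T43 with Ttf/T43H in 15-day testes sets the 2 chromosomes 17 side by side in a whole organ at the age when the first cells reach pachytene. Of the 8 largest rises that the naming rule took, 6 were genes of chromosome 17. The immunoproteasome gene Psmb9 rose by 3.48 ± 0.23 (11.1-fold, adjusted p = 0.0018, n = 3 and 3), the peptide transporter genes Tap1 and Tap2 rose by 2.32 ± 0.15 and 1.89 ± 0.08, the class I gene H2-Bl rose by 2.52 ± 0.24, and Msrb1 and Znrd1as rose by 1.07 ± 0.12 and 1.03 ± 0.20. Over proximal 17 as a whole 17 of 274 genes rose, 21 fell and 236 did not pass (31 and 33 adjusted over the set alone, adjusted p = 0.91). Ezr, Qk and Sox8 rose by 0.77 ± 0.08, 0.60 ± 0.06 and 0.84 ± 0.08, and Tbp fell by 0.58 ± 0.07. On other chromosomes, Tmem117 and Fam171b rose by 1.53 ± 0.15 and 0.91 ± 0.19.

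Late meiotic genes were lower in t12/T43 testes. Of 28 mid-late pachytene genes 9 fell, 1 rose and 18 did not pass (20 and 1 adjusted over the list alone), with a median of -0.68 (adjusted p = 3.8e-09, and adjusted p = 0.28 with an estimated correlation). The acrosomal gene Dkkl1, Nme5, Clgn, a chaperone of sperm proteins, and Crem, of the spermatid list, fell by 1.68 ± 0.24, 1.37 ± 0.19, 0.69 ± 0.11 and 0.77 ± 0.17. The dynein gene Dnah8, Pabpc6, Adam32 and Hspb9 fell by 2.64 ± 0.30, 2.90 ± 0.24, 2.73 ± 0.46 and 3.41 ± 0.65. Dnah8 and Pabpc6 are on chromosome 17, where the 2 carriers themselves differ, so their falls need not reflect stage. Adam32 and Hspb9 are on chromosomes 8 and 11. Of 17 piRNA genes 3 fell (13 adjusted over the list alone, adjusted p = 2.6e-07, and adjusted p = 0.28 with an estimated correlation), with Tdrd5, Tdrd9 and Gtsf1 at -0.83 ± 0.17, -0.54 ± 0.09 and -0.42 ± 0.07. Of 4 spermatid genes 1 fell (4 adjusted over the list alone, adjusted p = 0.0029, and adjusted p = 0.28 with an estimated correlation), and the list had an adjusted p of 0.088 with no filter. Of 20 recombination genes 3 fell (7 fell and 1 rose adjusted over the list alone, adjusted p = 0.036, and adjusted p = 0.48 with an estimated correlation), with Cntd1, Psmc3ip and Msh4 at -0.85 ± 0.14, -0.58 ± 0.11 and -0.40 ± 0.08. That list lost its call without Ttf/T43H replicate 1 (0.087) or t12/T43 replicate 3 (0.15). Syce1, of the synaptonemal complex, and H2ax, a histone gene of the DNA damage response, fell by 0.37 ± 0.07 and 0.33 ± 0.07. Of 6 retrocopies of X genes none passed over all genes in limma and 3 fell adjusted over the list alone (adjusted p = 0.0092, adjusted p = 0.28 with an estimated correlation, and 0.069 after quantile normalization).

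Genes of both sex chromosomes were higher in t12/T43 testes. Of 316 X genes 19 rose, none fell and 297 did not pass (29 rose adjusted over the set alone), with a median of 0.17 (adjusted p = 7.4e-18, and adjusted p = 0.75 with an estimated correlation). Of 16 X housekeeping genes 2 rose (6 adjusted over the list alone, adjusted p = 1.4e-04) and of 9 X germ cell genes 1 rose (6 adjusted over the list alone, adjusted p = 1.8e-04). The cohesin gene Stag2, Cul4b, Yipf6, Nxt2, Tex11, which is needed for synapsis, and Zfp711 rose by 0.32 ± 0.04, 0.29 ± 0.05, 0.35 ± 0.05, 0.39 ± 0.06, 0.32 ± 0.06 and 0.26 ± 0.04. The Y list had a median of 0.38, with all 4 genes higher adjusted over the list alone (adjusted p = 0.0080), and Zfy2 and Usp9y had changes of 0.48 ± 0.13 and 0.25 ± 0.07 (adjusted p = 0.075 each over all genes). These 3 lists had an adjusted p = 0.28 with an estimated correlation. The X level was higher in each of the 3 t12/T43 testes (0.34, 0.36 and 0.41) than in any of the 3 Ttf/T43H testes (0.10, 0.15 and 0.25), with a two-sided exact permutation p of 0.1, the smallest possible.

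The Sertoli list had a median of 0.10 in the same comparison, with 1 of 18 genes higher (1 adjusted over the list alone, adjusted p = 0.0080, and adjusted p = 0.52 with an estimated correlation), and lost its call without Ttf/T43H replicate 1 (0.077) or t12/T43 replicate 3 (0.062). The Leydig list stood at -2.39, -0.32 and 0.20 in the Ttf/T43H testes and at -1.26, -1.90 and 0.26 in the t12/T43 testes. Limma called 98 genes higher and 358 lower in t12/T43 testes among 9134 (2364 with an unadjusted p under 0.05, where chance gives 457), of which 113 changed at least 2-fold. The count was 22, 12 and 900 without Ttf/T43H replicate 1, 2 and 3, and 9 and 17 without t12/T43 replicate 2 and 3, and 4 of the 34 called genes named kept their call in every fit that left out 1 array. On simulated data of 9134 genes with 200 changed, 92% of those changed 2-fold and 100% of those changed 4-fold were recovered. The simulation held no deviation shared by the genes of an array, so it does not cover the dependence on single arrays seen here.

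Comparing Ttf/T43H with C57BL/6J testes at 15 days asks what this carrier changes against a normal testis, in a design where carriers and controls also differ in strain, since the carriers have a C57BL/10J background. Proximal 17 was lower: 76 of 274 genes fell, 5 rose and 193 did not pass (112 and 13 adjusted over the set alone), with a median of -0.20. The call, at an adjusted p of 2.2e-15, held with an estimated correlation (9.7e-04), as it did for t12/T43 testes, and no other set call of any comparison held. The sperm tail gene Rsph1, the Polycomb gene Ring1, Telo2 and Rnf8 fell by 1.71 ± 0.09, 1.07 ± 0.05, 0.90 ± 0.04 and 0.73 ± 0.05 (n = 3 and 2), and the glyoxalase gene Glo1 rose by 1.22 ± 0.07. Of 11 t complex genes 4 fell (4 fell and 1 rose adjusted over the list alone, adjusted p = 0.031, and adjusted p = 0.43 with an estimated correlation), among them Tbp, the chaperonin gene Tcp1 and Tcp11 at -0.70 ± 0.07, -0.33 ± 0.08 and -1.50 ± 0.29. The t complex list lost its call without Ttf/T43H replicate 3 (0.069), C57BL/6J replicate 1 (0.054) or 2 (0.25).

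Large single-gene differences lay across the genome in the same comparison. Smpx, on the X, fell by 10.29 ± 0.05, from a mean of 12.70 in C57BL/6J to 2.42 in Ttf/T43H. Plbd1, Cldn23, the interferon-induced gene Ifi204, Loxl2 and Apoc2 rose by 6.30 ± 0.14, 4.15 ± 0.15, 3.66 ± 0.13, 3.57 ± 0.32 and 2.51 ± 0.20. The ribosomal protein gene Rps6 and Septin12 fell by 3.26 ± 0.08 and 2.60 ± 0.13, and Pgk2 was 5.66-fold lower. Of 4 Y genes Zfy2 and Usp9y rose by 1.15 ± 0.14 and 0.59 ± 0.07 (2 adjusted over the list alone, adjusted p = 0.031, and adjusted p = 0.70 with an estimated correlation), a list call lost without Ttf/T43H replicate 3 (0.086) or C57BL/6J replicate 2 (0.053). Of 9 X germ cell genes 2 rose (4 adjusted over the list alone, adjusted p = 0.022, and adjusted p = 0.70 with an estimated correlation), a call lost without C57BL/6J replicate 1 (0.061). The X as a whole had a median of 0.01 and a mean of -0.01, with 14 genes higher and 4 lower (adjusted p = 0.80).

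Early prophase lists were a little higher in Ttf/T43H testes. Of 15 leptotene and zygotene genes 1 rose (4 rose and 1 fell adjusted over the list alone, adjusted p = 0.022), with Dmc1 at 0.54 ± 0.09, and of 15 synapsis genes the cohesin gene Smc3 rose by 0.26 ± 0.06 (3 adjusted over the list alone, adjusted p = 0.029). Both had an adjusted p = 0.73 with an estimated correlation. The first lost its call without C57BL/6J replicate 2 (0.058), the second without Ttf/T43H replicate 1 (0.068) or C57BL/6J replicate 2 (0.059). Of 13 stress genes Jun and Egr1 fell by 0.41 ± 0.07 and 1.19 ± 0.23 (2 adjusted over the list alone, adjusted p = 0.022, and adjusted p = 0.40 with an estimated correlation). Of 10 macrophage and blood genes Adgre1 fell by 1.27 ± 0.23 (1 adjusted over the list alone, adjusted p = 0.031, and adjusted p = 0.80 with an estimated correlation), a call lost without Ttf/T43H replicate 1 (0.13) or 2 (0.11) or C57BL/6J replicate 1 (0.088) or 2 (0.053). Trf, a Sertoli transferrin gene, and Hsd3b1 fell by 1.33 ± 0.19 and 0.94 ± 0.16. Limma called 353 genes higher and 429 lower (2318 with an unadjusted p under 0.05), of which 111 changed at least 2-fold. The count was 490 and 350 without Ttf/T43H replicate 1 and 2 and 219 and 176 without C57BL/6J replicate 1 and 2, and 13 of the 26 called genes named kept their call in every fit that left out 1 array. On simulated data with 200 changed genes, 95% of those changed 2-fold and 96% of those changed 4-fold were recovered.

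**Figure D3:**
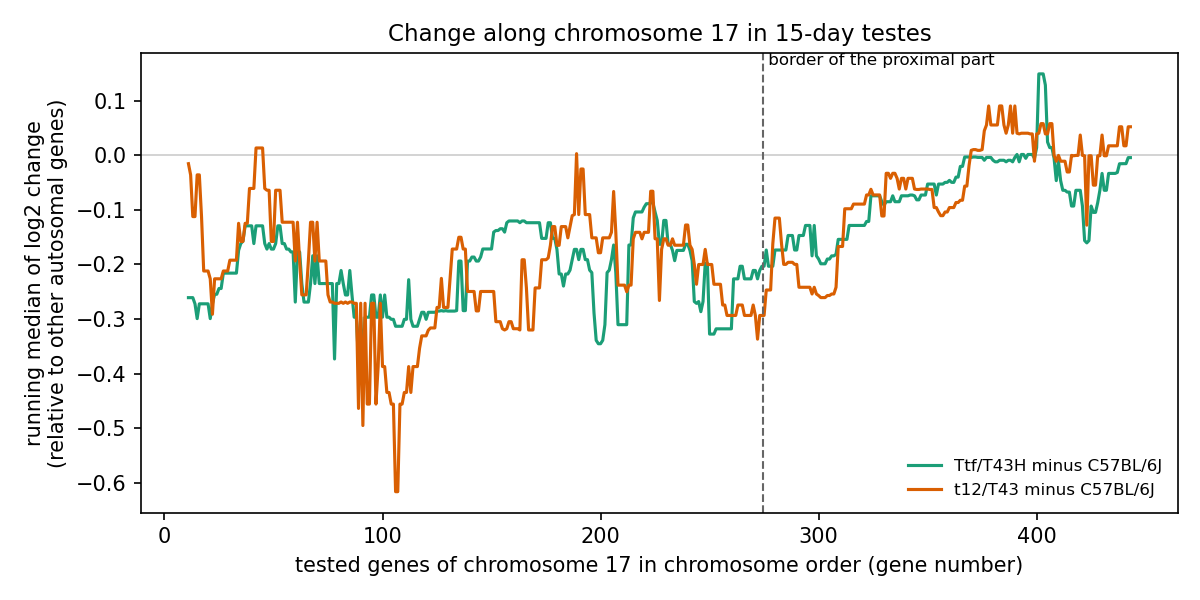
Running median over 21 genes of the change in carrier against C57BL/6J testes, in log2 units relative to autosomes other than 16 and 17, along the tested genes of chromosome 17 in their order from the centromere (1 line per carrier, dashed line at the border of the proximal part). The medians of Ttf/T43H and t12/T43 are -0.21 and -0.19 over 274 proximal genes and -0.06 and -0.06 over 179 distal genes, and both lines stay below 0 for some way past the border.

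Comparing t12/T43 with C57BL/6J testes carries the same confound of strain. Proximal 17 was lower: 105 of 274 genes fell, 17 rose and 152 did not pass (123 and 23 adjusted over the set alone), with a median of -0.18 (adjusted p = 4.0e-09, and 0.0038 with an estimated correlation). Rsph1, Telo2, Hagh and Tbp fell by 2.88 ± 0.09, 1.05 ± 0.04, 1.11 ± 0.06 and 1.28 ± 0.07 (n = 3 and 2), while Psmb9 and Tap2 rose by 3.74 ± 0.26 and 2.14 ± 0.09. Late meiotic genes were lower: 20 of 28 in the mid-late pachytene list fell, 2 rose and 6 did not pass (23 and 2 adjusted over the list alone), with a median of -1.02 (adjusted p = 2.0e-07, and adjusted p = 0.41 with an estimated correlation). Dkkl1, the acrosomal protease gene Acr, Nme5 and Pgk2 fell by 2.48 ± 0.27, 2.45 ± 0.23, 1.81 ± 0.21 and 2.75 ± 0.19, and Adam32, Pabpc6 and Dnah8 fell by 3.85 ± 0.52, 3.89 ± 0.27 and 3.14 ± 0.34. Of these, Pgk2, Pabpc6 and Dnah8 are on chromosome 17. Of 17 piRNA genes 6 fell (9 adjusted over the list alone, adjusted p = 0.0030, and adjusted p = 0.48 with an estimated correlation), with Tdrd5 and the RNA helicase gene Ddx25 at -1.02 ± 0.19 and -1.07 ± 0.21.

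Sex-linked genes were higher in t12/T43 testes than in C57BL/6J testes. Of 316 X genes 82 rose, 3 fell and 231 did not pass (102 and 4 adjusted over the set alone), with a median of 0.17 (adjusted p = 9.4e-10, and adjusted p = 0.56 with an estimated correlation). Of 9 X germ cell genes 8 rose (9 adjusted over the list alone, adjusted p = 4.1e-05) and of 16 X housekeeping genes 5 rose (6 adjusted over the list alone, adjusted p = 0.0016). Tex16, Magea5, Cul4b, Stag2 and the histone demethylase gene Kdm6a rose by 0.55 ± 0.06, 0.68 ± 0.09, 0.53 ± 0.06, 0.45 ± 0.05 and 0.54 ± 0.07. All 4 Y genes rose (4 adjusted over the list alone, adjusted p = 0.0028), with Zfy2, Usp9y, Uty and Eif2s3y at 1.63 ± 0.14, 0.84 ± 0.07, 0.83 ± 0.24 and 0.28 ± 0.08. These 3 lists had an adjusted p = 0.31 with an estimated correlation. Of 13 stress genes 3 fell (4 adjusted over the list alone, adjusted p = 0.017, and adjusted p = 0.31 with an estimated correlation). Smpx fell by 10.30 ± 0.05, and Plbd1, Cldn23 and Ifi204 rose by 6.53 ± 0.14, 4.52 ± 0.15 and 3.89 ± 0.13. Stra8 and Dmc1 rose by 0.40 ± 0.07 and 0.57 ± 0.09.

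No list of somatic cells was called in the same comparison. Of 18 Sertoli genes 3 rose and 1 fell (4 and 1 adjusted over the list alone, adjusted p = 0.067), with Wt1 at 0.24 ± 0.05 and Trf at -1.54 ± 0.19. Of 7 Leydig genes Hsd3b1 fell by 0.83 ± 0.16 (1 adjusted over the list alone, adjusted p = 0.20). Of 13 peritubular and endothelial genes Col1a1 and Tagln fell by 0.83 ± 0.18 and 0.39 ± 0.06 (2, 0.095), and of 10 macrophage and blood genes Adgre1 and Fcer1g fell by 0.94 ± 0.23 and 0.47 ± 0.13 (2, 0.083). Limma called 960 genes higher and 1034 lower (3348 with an unadjusted p under 0.05), of which 274 changed at least 2-fold. The count was 1241 without t12/T43 replicate 2 and 596 and 879 without C57BL/6J replicate 1 and 2, and 23 of the 37 called genes named kept their call in every fit that left out 1 array. On simulated data with 200 changed genes, 92% of those changed 2-fold and 99% of those changed 4-fold were recovered.

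The last comparison tested whether the difference between t12/T43 and Ttf/T43H differed between sorted pre-mid-pachytene cells and testes. Of the 78 genes called, 61 lay below the filter level in both carriers' testes and 6 in both carriers' sorted cells. For 65 this was so in 1 tissue only, so that their difference restates the change in the other tissue. The spermatid list had a median difference of -3.70, with 6 of 24 genes called (18 adjusted over the list alone, adjusted p = 3.1e-25, and adjusted p = 0.16 with an estimated correlation). In both carriers' testes 20 of the 24 lay below that level, where a change would hardly show. Tnp2, Prm2, Gapdhs and Spata19 differed by -5.82 ± 0.53, -4.45 ± 0.40, -4.88 ± 0.50 and -4.79 ± 0.57. They stood at 2.31, 2.27, 1.92 and 2.23 in Ttf/T43H testes. Psmb9, Tap1 and Tmem117 differed by -3.24 ± 0.27, -2.31 ± 0.29 and -1.51 ± 0.19 and stood at 2.66, 1.65 and 2.48 in sorted t12/T43 cells. Cd36 differed by 2.63 ± 0.39 and stood at 2.91 in t12/T43 testes. Proximal 17 differed by a median of -0.18, with 6 of 312 genes called (7 adjusted over the set alone, adjusted p = 3.0e-04, and adjusted p = 0.97 with an estimated correlation), a call lost without sorted Ttf/T43H replicate 2 (0.39). The t complex list differed by a median of -0.22, with 2 of 16 genes called (4 adjusted over the list alone, adjusted p = 0.019, and adjusted p = 0.18 with an estimated correlation). It lost its call without sorted Ttf/T43H replicate 2 (0.068) or 3 (0.053), sorted t12/T43 replicate 1 (0.18) or 3 (0.075), or t12/T43 testis replicate 1 (0.097) or 3 (0.051).

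With no member called by limma, the X germ cell list differed by a median of -0.30 (adjusted p = 0.014), the piRNA list by 0.44 (0.0052) and the Leydig list by 1.85 (0.04997, just under the threshold), each with an adjusted p = 0.95 with an estimated correlation. Below the filter level in both carriers of 1 tissue only were 5 of 16, 1 of 17 and 2 of 8 of their genes, and 62 of 312 on proximal 17 and 4 of 16 in the t complex list. The first 2 lost their call without sorted Ttf/T43H replicate 2 (0.77 and 0.34) or t12/T43 replicate 1 (0.17 and 0.17). The Leydig call was lost without sorted Ttf/T43H replicate 2 (0.068) or 3 (0.43), sorted t12/T43 replicate 2 (0.13) or 3 (0.22), Ttf/T43H testis replicate 2 (0.063) or 3 (0.40), or t12/T43 testis replicate 1 (0.13) or 2 (0.20). The X as a whole had an adjusted p of 0.90. It was called without sorted Ttf/T43H replicate 2 (5.5e-04, in the other direction) or 3 (0.016) or t12/T43 replicate 3 (0.036), and turned direction without sorted t12/T43 replicate 1 (0.20) or 2 (0.98), Ttf/T43H testis replicate 1 (0.94) or t12/T43 testis replicate 3 (0.96). Limma called 7 genes higher and 71 lower among 10623 (812 with an unadjusted p under 0.05, where chance gives 531). The count was 429 without sorted t12/T43 replicate 2, 46, 46 and 47 without Ttf/T43H testis replicate 1, 2 and 3, and 46, 49 and 46 without t12/T43 testis replicate 1, 2 and 3, and all 8 genes named kept their call in every fit that left out 1 array. On simulated data of 10623 genes with 200 changed, 22% of those changed 2-fold and 68% of those changed 4-fold were recovered.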

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

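In this part, both tests of other cells' RNA behind the spermatid transcripts were chosen only after the result was seen.

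The difference between t12/T43 and Ttf/T43H carriers was measured in both sorted spermatocytes and 15-day testes, and 78 genes passed the test of whether that difference itself differed between the tissues. The same test called the spermatid list (median difference -3.70), proximal chromosome 17 (-0.18), the X germ cell list (-0.30), the t complex list (-0.22), the Leydig list (1.85) and the piRNA list (0.44), and none of these calls held with an estimated correlation. Of the 78 genes, 65 lay below the filter level in both carriers of 1 tissue only, as did 20 of the 24 spermatid genes in testes. Their difference restates the change in the other tissue and does not show that the tissues respond differently. As many genes passed in 11 of 100 pairs of splits of the carrier arrays, the real pair included, but the other 10 keep the real split, and its difference, in 1 tissue, so this share cannot tell whether chance can be excluded; the highest other, 457, several times the real count, came from a pair with the real testis split, and the 81 pairs that split both tissues gave at most 5.

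Transcripts of spermatids were far lower in t12/T43 than in Ttf/T43H sorted spermatocytes. A lower share of spermatocytes filled by all other cell types alike would raise spermatid transcripts, so the fall itself argues against it. The median change of the Sertoli list exceeded that of the spermatid list by 4.28 (95% bootstrap interval over genes, 2.996 to 4.54). That gap holds the same fall, so it adds no independent support. RNA of spermatids carried into the pre-mid-pachytene sorts stays open, and the levels go with it. In C57BL/10J the list was lower in mid-late than in pre-mid-pachytene cells by a median of -2.03, the reverse of a rise with stage. The interval over genes, from 2 arrays against 2, was -2.69 to -0.56. The camera set test had an adjusted p of 0.13, with 6 of 24 genes falling. All 24 genes reached the filter level in C57BL/10J pre-mid-pachytene cells and 4 in C57BL/6J testes of 15 days, before spermatids form. Prm1 stood at 14.52 and 2.68 there. Carry-over, which the gate on that stage would have to let through, may account for part or all of the levels. Only 1 of the 10 splits of the 6 arrays, the real one, called as many genes (73, highest other 2), and 10 splits are too few for a share under 0.05. The carriers' genotype, a difference the design names, remains open and untested, and genotype and carry-over need not exclude each other.

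Proximal chromosome 17 genes were lower in both carriers than in the controls, least firmly in sorted Ttf/T43H cells. There the level was -0.55 ± 0.31 against -0.21 ± 0.01 in C57BL/10J (SD), and the camera call was lost without Ttf/T43H replicate 3 (adjusted p = 0.12). A strain difference between C57BL/6J and C57BL/10J as the whole cause is argued against, since over 238 genes the changes of t12/T43 against C57BL/6J in testes and against C57BL/10J in sorted cells had a rank correlation of 0.52, above random autosomal sets (0.16 to 0.41). Sequence variants under the probes of the carriers' chromosome 17 could account for part, since the same correlation for Ttf/T43H was 0.35, also above random sets (-0.0018 to 0.25). Silencing in spermatocytes cannot be told apart from these. The rank correlation of the testis change with spermatocyte preference was -0.32 for t12/T43, within random sets (-0.36 to -0.10), and -0.35 for Ttf/T43H, below them (-0.06 to 0.20). Preference here was the level in C57BL/10J pre-mid-pachytene cells minus that in the other carrier's testes. Proximal 17 was lower in both carriers' testes, so a fall shared by them lowers this correlation by itself. It therefore cannot decide on silencing. The correlations are across genes, which are not independent replicates, and the genotype itself remains open.

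X-linked genes were slightly higher in t12/T43 than in Ttf/T43H testes. To test for a different mix of cell stages, 10000 autosomal sets were matched with 20 neighbours per gene on change through pachytene, spermatocyte preference and level. The median X change of 0.17 over 269 genes lay above the range of these sets (0.10 to 0.12). That range reflects only the choice among neighbours, not the spread between arrays or between X genes. The match also fell short: the median change through pachytene was -4.03 for the X and -3.84 for the matched genes. The test therefore cannot decide whether a stage mix is the whole cause. A stage mix may account for much of the change, as the matched sets had a median of 0.11 themselves. The X set's call was lost with an estimated correlation (adjusted p = 0.75). Of the 10 splits of the 6 testes 1, the real one, gave a median X shift as large (0.15, highest other 0.11), and 10 splits are too few for a share under 0.05. The carriers' genotype, a difference the design names, stays open and untested, as does a stage mix that the matched sets did not capture.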

How the results depend on the processing

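In this part, the setting without both arrays that stand apart was chosen only after the data were seen. Apart from fits that left out 1 array, 382 set results and 1773 gene results kept their direction and side of the threshold, 92 and 211 lost their call, 8 and 12 gained one, and 4 and 2 turned direction. In fits that left out 1 array, 405 and 904 kept both, 50 and 348 lost a call, 6 and 2 gained one, and 10 sets and no gene turned direction. Averaging several probe sets of a gene, or testing each one, was not run, since each gene has 1 probe set. Signal over background limits what low values can show, and dropping the filter added genes at that level. Where a result changed below, the cause was not tested unless a setting tests fewer genes or arrays by construction.

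With an estimated correlation, comparing t12/T43 with Ttf/T43H sorted cells gave adjusted p-values of 1.0 for proximal 17, 0.52 for the mid-late pachytene list, 0.18 for the spermatid and t complex lists, and 0.71 for the Sertoli (0.7136) and Leydig (0.7054) lists. Proximal 17 had 0.927 for Ttf/T43H and 0.984 for t12/T43 against C57BL/10J, 0.9998 for t12/T43 against mid-late cells and 0.970 for the difference between tissues. The X had 0.975 for mid-late against pre-mid-pachytene cells, 0.9995 and 0.9998 for the 2 carriers against mid-late cells (where the Sertoli and stress lists had 0.449 and 0.386, and the Leydig list 0.386 in t12/T43), 0.749 for t12/T43 against Ttf/T43H testes and 0.558 for t12/T43 against C57BL/6J testes. In t12/T43 against Ttf/T43H testes the X housekeeping, X germ cell, Y linked, retrocopy, mid-late pachytene, spermatid and piRNA lists each had 0.279, the recombination list 0.476 and the Sertoli list 0.517.

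With a border of proximal 17 nearer the centromere, it had 0.0522 for Ttf/T43H against C57BL/10J and 0.234 for t12/T43 against mid-late cells. With no filter, the counts were 15 for t12/T43 against Ttf/T43H sorted cells, 8867 for mid-late against pre-mid-pachytene, 9775 and 9989 for Ttf/T43H and t12/T43 against mid-late cells, and 149 for t12/T43 against Ttf/T43H testes, proximal 17 had 0.436 for t12/T43 against mid-late cells, and the spermatid list 0.0881 in t12/T43 against Ttf/T43H testes. In t12/T43 against Ttf/T43H sorted cells the X was called without multicopy families (0.0361), after quantile normalization (0.0450), after centring (0.0221) and with the replicate block (0.0453). Quantile normalization gave the retrocopy list 0.0688 in t12/T43 against Ttf/T43H testes.

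Array weights, whose estimation did not converge, gave counts of 2215, 5113 and 4103 for t12/T43 against Ttf/T43H, Ttf/T43H against C57BL/10J and t12/T43 against C57BL/10J sorted cells, 1945 and 2313 for t12/T43 against Ttf/T43H and Ttf/T43H against C57BL/6J testes, and 3837 for the difference between tissues, and turned Zfy2 in t12/T43 against Ttf/T43H sorted cells to -0.30. With only the 2 groups compared the counts were 12 and 420 for t12/T43 against Ttf/T43H and against C57BL/10J sorted cells, and 36 and 490 for t12/T43 against Ttf/T43H and Ttf/T43H against C57BL/6J testes. A 2-fold minimum left 113, 111 and 274 genes for t12/T43 against Ttf/T43H, Ttf/T43H against C57BL/6J and t12/T43 against C57BL/6J testes.

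Replicate numbers were not taken to pair the samples, since the labels give no pairing and not every same-number correlation of deviations from group means was over 0.1. Between the 2 carriers these were 0.25, 0.02 and -0.35 in sorted cells and 0.49, 0.04 and 0.68 in testes. In testes they were 0.38 and 0.17 for Ttf/T43H with C57BL/6J and 0.26 and -0.07 for t12/T43 with C57BL/6J, and 5 of the 7 pairs matched their own number best, which leaves a shared source of the numbers unsettled there. With the replicate block the counts were 0 (limma, 869 unadjusted), 18 and 400 for t12/T43 against Ttf/T43H, Ttf/T43H against C57BL/10J and t12/T43 against C57BL/10J sorted cells, and 1703 and 2139 for t12/T43 against Ttf/T43H and Ttf/T43H against C57BL/6J testes, and in the last the X turned direction (0.797) and the Y linked and t complex lists had 0.0849 and 0.0795.

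Without both arrays that stand apart, t12/T43 against Ttf/T43H sorted cells gave a count of 0 (limma, 825 unadjusted), 0.482 for proximal 17, 7.6e-06 for the X, 0.978 in the other direction for the Sertoli list, 0.131 for the Leydig (0.1307) and t complex (0.1313) lists, and -0.16 for Zfy2, also turned. The count was 542 for Ttf/T43H against C57BL/10J, whose X had 1.6e-05. The X had 0.384 for t12/T43 against C57BL/10J and 0.967 for the difference between tissues, both turned, the Leydig list had 0.0668 for t12/T43 against mid-late cells, and proximal 17 had 0.0303 for Ttf/T43H against mid-late cells and 0.641 for the difference between tissues.

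Leaving out 1 array gave these lowest and highest counts: 13 and 411 for t12/T43 against Ttf/T43H, 0 (limma, 850 unadjusted) and 368 for Ttf/T43H against C57BL/10J, and 141 and 1391 for t12/T43 against C57BL/10J sorted cells; 9 and 900 for t12/T43 against Ttf/T43H, 176 and 827 for Ttf/T43H against C57BL/6J, and 596 and 1644 for t12/T43 against C57BL/6J testes; and 46 and 429 for the difference between tissues. Adjusted p-values in t12/T43 against Ttf/T43H sorted cells ran from 9.8e-07 to 0.685 for proximal 17, 3.8e-12 to 0.979 for the X (turned), 7.2e-05 to 0.539 for the Sertoli list, 2.5e-04 to 0.0935 for the Leydig list and 4.2e-04 to 0.0634 for the t complex list. They ran from 3.7e-09 to 0.121 for proximal 17 and 8.5e-05 to 0.714 for the X in Ttf/T43H against C57BL/10J, 0.290 to 0.928 for the X in t12/T43 against C57BL/10J, 0.0272 to 0.369 for proximal 17 in Ttf/T43H against mid-late cells, and 0.0224 to 0.0782 for the Leydig list in t12/T43 against mid-late cells. In testes they ran from 0.232 to 0.850 for the X in Ttf/T43H against C57BL/6J, and from 0.0128 to 0.154 for the recombination list and 0.0012 to 0.0766 for the Sertoli list in t12/T43 against Ttf/T43H. For the difference between tissues they ran from 8.9e-06 to 0.387 for proximal 17 and 5.5e-04 to 0.981 for the X.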

Other observations

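In this part, the test of genes changed in both tissues was chosen only after the result was seen. Apart from the planned splits of the testis arrays, the other values are given without a test.

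Levels of single genes of antigen presentation and interferon response, looked up after the results were seen, are given here. In testes, mean levels of Psmb9 were 4.06 in Ttf/T43H, 7.54 in t12/T43 and 3.79 in C57BL/6J, those of Tap1 2.47, 4.80 and 2.47, and those of H2-Bl 2.90, 5.42 and 2.63, while Psmb8, a gene of the same complex as Psmb9, stood at 3.29, 3.53 and 3.41, below the filter level, where a change would hardly show. In the same testes H2-D1 stood at 11.43, 11.18 and 10.92, Tapbp at 9.38, 9.17 and 9.54, B2m at 11.13, 11.34 and 11.49 and Ly6e at 10.40, 10.16 and 10.47. In sorted cells Psmb9 stood at 2.42, 2.66 and 2.31 in Ttf/T43H, t12/T43 and C57BL/10J pre-mid-pachytene cells, near the low end of the arrays. H2-K1, a class I gene, stood at 10.27, 11.02 and 13.47 in the same sorted groups and at 9.65 in mid-late cells, and at 10.30, 11.10 and 10.88 in Ttf/T43H, t12/T43 and C57BL/6J testes. B2m, the light chain of class I molecules, stood at 9.05, 9.77, 9.41 and 6.23 in the 4 sorted groups.

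Levels of spermatid transcripts differed widely between the sorted groups. Prm1 stood at 13.38, 9.44, 14.52 and 12.24 in Ttf/T43H, t12/T43, C57BL/10J pre-mid and C57BL/10J mid-late cells, Tnp1 at 11.36, 7.52, 12.90 and 9.87, Smcp at 11.25, 7.24, 12.95 and 10.38, Tnp2 at 10.07, 4.24, 10.67 and 6.22, Prm2 at 10.03, 5.58, 12.49 and 8.71, and Gapdhs at 9.93, 5.05, 11.74 and 8.63, while Prm1 stood at 2.71, 2.70 and 2.68 in Ttf/T43H, t12/T43 and C57BL/6J testes of 15 days, an age before spermatids form. Of the 24 genes of the list on the array, 24, 20, 24 and 24 reached the filter level in the mean of the sorted groups and 4 in each testis group, and 0 of the 24 stand in another list. Akap4, a sperm tail gene outside it, is in the X germ cell list. It stood at 10.42, 6.66, 13.01 and 10.36 in the sorted groups.

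Between t12/T43 and Ttf/T43H testes, 1 of the 10 splits of the 6 arrays, the real one, called as many genes (456, highest other 0), and 10 splits are too few for a share under 0.05.

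Outside chromosomes 16 and 17, 10 genes were higher in Ttf/T43H against both control strains, in testes and in sorted cells, where independent lists among 7523 genes would share 2.14 (Fisher's exact test, two-sided, p = 4.2e-05, adjusted 5.5e-05 over 4 tests), among them Apoc2, Emp1 and Ifi202b. Another 8 were lower in both, Smpx among them, against 1.81 for independent lists (same exact test, p = 3.7e-04, adjusted 3.7e-04). Both overlaps rest on calls in sorted Ttf/T43H cells, which depended on single arrays. Limma called 199 genes there, and 36, 368 and 75 without Ttf/T43H replicate 1, 2 and 3. The overlaps were not tested with an array left out. For t12/T43 54 were higher and 62 lower, against 29.8 and 16.4. A difference carried along with the carrier stock may account for some of these genes, and other causes shared by both tissues stay open. The 62 lower in t12/T43 include Hspb9 and Odf4. For such genes, the lower late germ cell transcripts described above in both t12/T43 tissues are 1 of these causes. The fall of Smpx was not seen in Mbtps2, next to it on the X, which stood at 9.72, 10.04 and 9.73 in Ttf/T43H, t12/T43 and C57BL/6J testes. Cnksr2, on its other side, stood at 3.075, 3.25 and 3.075, below the filter level, where a fall would hardly show. Eif1ax, the gene after Cnksr2 on the array, stood at 9.69, 9.89 and 9.68.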
